A study of Mus musculus with 2 samples.

How the data were processed

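The samples were total RNA from ATDC5, a mouse cell line that can undergo chondrogenic differentiation. Serum-starved cells received cycloheximide (CHX), a blocker of protein synthesis, at 10 µg/ml for 30 min, and then either PBS or recombinant human Nell-1 protein at 100 ng/ml for a further 30 min. RNA was purified with TRIzol and a silica column, treated with DNase, labelled with biotin and hybridised to Affymetrix mouse expression arrays, per the labels' protocols. One-colour arrays of this type read each transcript with groups of short probes called probe sets, mostly placed near the 3' end. The groups were CHX+PBS with 1 array and CHX+Nell-1 with 1 array.

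The deposited values are intensities, that is, linear MAS5 signals per probe set. Affymetrix Expression Console and MAS5 are named in the submitters' processing notes, and the versions are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and multiplies each array by 1 factor to reach a common trimmed mean. Tested on the deposited table, the 2% trimmed mean was 500.0 on both arrays. Each table column was assigned to its sample by the sample name. Present and absent detection calls were not used here, so background was judged from signal alone. The mismatch correction gives small positive signals to transcripts at low abundance, and ratios of such signals are unstable.

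Of 45101 probe sets, 64 were Affymetrix controls and were kept apart. Of the other 45037, the platform annotation gave 1 gene symbol to 34945, several to 932 and none to 9160. Gene IDs of 34741 of the 34945 were found in a RefSeq gene table of assembly GRCm38.p6, which was used for symbols only. Probe sets with several symbols or none entered counts of probe sets, and no gene was named from them. A gene was represented by its probe set with the highest mean signal over both arrays, which gave 18193 genes. Probe sets of a gene that disagreed are described where they occur.

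The measure was the log2 ratio of the CHX+Nell-1 over the CHX+PBS signal as deposited. With 1 array per group there is no estimate of the spread between cultures, so no test was run and no p-value, standard error or confidence interval is given. The threshold of 1.5-fold is the one the submitters state for their own filter. Counts were made over all probe sets and over the 22519 whose mean signal over both arrays was at or above the median of 64.3. As a yardstick, the robust SD (from the median absolute deviation) of the log2 ratios was computed in 10 equal bins of mean signal. It mixes measurement noise with real differences. The number of arrays, and not the number of probe sets, limits the precision.

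Measurement noise was also examined through genes with at least 2 probe sets above the median signal. The share of same-sign log2 ratios between the 2 brightest probe sets was compared with 1000 random re-pairings within 10 bins of signal. In total 28 gene lists with 452 genes were fixed before the data were examined, and 410 of the genes were measured by a probe set with 1 symbol. The other 42 were not analysed here. The median log2 ratio of each list was placed among the medians of 10000 random gene lists of the same size, matched on 20 bins of mean signal. A list was said to stand apart below percentile 2.5 or above percentile 97.5. Chance alone would place 1.4 of 28 lists there if genes were independent. The percentile describes these 2 arrays and is not a test of the treatment.

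Genes named below were chosen by a rule fixed before the data were examined, except Csrnp1, Spred1 and the genes with a mean signal over 1000 in the closing section, which were chosen after their values were seen. The rule took genes fixed by name, the 10 highest and 10 lowest genes above the median signal after adding 17.9 (the 25th percentile of the mean signal) to both signals, up to 10 genes whose probe sets above the median signal all passed 1.5-fold the same way, and up to 4 members of each list above the median signal with the largest ratios. Printed ratios carry no added constant unless stated.

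The code was tested on simulated arrays with the real mean signals and the observed spread per bin. Of 200 probe sets above the median signal planted at 2-fold, 90.0% passed 1.5-fold in the planted direction. In the same simulation of this comparison 15.4% of 22306 unchanged probe sets above the median signal and 65.1% of 22499 unchanged probe sets below it also passed 1.5-fold. Because the simulated spread was taken from the observed ratios, these shares contain any real differences. Of 200 unchanged random lists 5.5% stood apart. The simulated noise was independent between probe sets, so this share does not hold for lists of genes that vary together.

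Alternatives were 4 rescalings (median centring, a repeated trimmed mean scaling, removal of a loess trend on signal, quantile normalization), an added or a floor value of 17.9, other signal filters, a 2-fold threshold, probe sets not marked as shared between transcripts, and the mean over a gene's probe sets. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.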

Results

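Gene expression was compared in ATDC5 chondrogenic cells after 30 min of Nell-1, a secreted glycoprotein with bone-forming activity, or of PBS, with protein synthesis blocked by CHX in both. The stated purpose was to find primary response genes, those that respond without new protein being made. The data are 2 arrays, 1 per group, with no replicate in either, so each ratio below compares 2 RNA samples and carries no error between cultures. Signals ranged from 0.0883 to 45842 on the CHX+PBS array, with a median of 69.8, and from 0.066 to 41205 on the CHX+Nell-1 array, with a median of 62.8.

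The arrays resembled each other closely for well-measured transcripts. Across the 22519 probe sets above the median signal, the log2 signals correlated at r = 0.975, and across all 45037 non-control probe sets at r = 0.927. Both values are across probe sets, which are not independent replicates. The robust SD of the log2 ratio was 0.21 in the brightest of 10 signal bins, 0.43 in the bin between signals of 121 and 282, and 2.23 in the bin between 13.2 and 23.8. Housekeeping genes differed little. Actb (beta-actin) measured 29110 with PBS and 27786 with Nell-1, a log2 ratio of -0.07, and the 12 measured reference genes had a median of -0.03, at percentile 43.0 of matched random lists. None of the 12 reached 1.5-fold. The nearest were Tfrc, the transferrin receptor, at 0.58 and Hprt, a purine salvage enzyme, at 0.34.

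**Figure D1:**
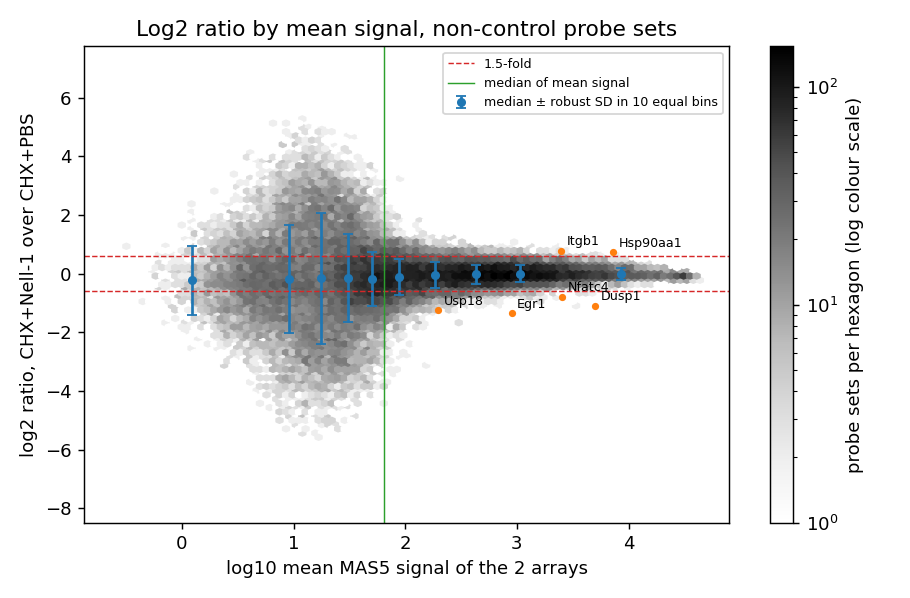
Each hexagon counts non-control probe sets by the log10 mean MAS5 signal of the 2 arrays (x axis) and the log2 ratio of CHX+Nell-1 over CHX+PBS (y axis), with the median and robust SD of 10 equal signal bins in blue, 1.5-fold as dashed lines and the median of the mean signal as a vertical line. The spread narrows from 2.23 in the third bin to 0.21 in the brightest, where the named genes Dusp1, Nfatc4, Hsp90aa1 and Itgb1 lie outside the dashed lines.

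Applying the 1.5-fold filter to every probe set selected 7896 that were higher and 10386 that were lower with Nell-1, together 40.6% of the 45037. The split was 9124 higher and 8969 lower after the loess trend on signal was removed, and 9082 and 9033 after quantile normalization. Both rescalings pull the ratios toward balance by construction, so they cannot show whether the imbalance is real. Median centring, which shifts every ratio alike, left 8177 higher and 10084 lower. Above the median signal 1344 were higher and 1910 lower, which is 14.4% of 22519. These counts were 1575 and 1630 with loess, 1601 and 1606 with quantile normalization, and 1491 and 1779 with median centring. Among genes above the median signal, 529 of 11600 were higher and 874 lower. The passing share depended on signal, from 77.9% in the third bin to 2.11% in the brightest bin, where 60 probe sets were higher and 35 lower. Probe sets for the same gene gave a partial check within each RNA sample. For 5195 genes with 2 or more probe sets above the median signal, the 2 brightest had the same sign in 68.6%, against at most 52.1% in 1000 random re-pairings. Of 352 such genes whose brightest probe set passed 1.5-fold, the second also passed the same way in 33.5%.

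The genes with the largest ratios above the median signal mostly had a low signal on one array. With 17.9 added to both signals, the 10 highest with Nell-1 included Dnajc22, a co-chaperone family member, with signals of 17.1 with PBS and 163 with Nell-1. Also among them were the taste receptor Tas1r3 (16.9 and 159), the centriole duplication gene Cep152 (10.1 and 122), the vomeronasal receptor Vmn1r44 (26.5 and 170) and the calcium-binding secretagogin gene Scgn (17.1 and 121). The rest of the 10 highest were Ccdc169, Tmem89, Ppp1r3f, the endothelial-haematopoietic transcription factor Etv2, and Baalc, with ratios of the plain signals from 4.19-fold for Ppp1r3f to 5.90-fold for Ccdc169. Their order depends on the added value and is not given. The 10 lowest by the same measure included Crybb2, a lens crystallin, at 203 with PBS and 16.5 with Nell-1. Others were Csdc2 (195 and 20.4), the cystatin Cst6 (193 and 21.7), Zdhhc11 (122 and 8.68) and the serine protease gene Prss12 (145 and 13.8). Zap70, a T-cell receptor kinase, had the brightest signals of the 10 lowest, 640 with PBS and 112 with Nell-1. The remaining 4 were Tex44, Tmem213, Scube1 and Dbil5. Of these 20 genes, Baalc alone had a second probe set above the median signal, and that one did not reach 1.5-fold.

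A narrower set passed 1.5-fold the same way on every probe set above the median signal, 46 genes higher and 47 lower with Nell-1. Shuffling the ratios among probe sets of similar signal 100 times gave a median of 11 and at most 22 higher genes, and a median of 21 and at most 36 lower. Another 61 genes had one probe set higher and another lower by 1.5-fold. The mean log2 ratio over probe sets, by which genes were picked, exceeded that of the brightest probe set where a dimmer one differed more. Crhr1, the corticotropin-releasing hormone receptor, had a mean of -1.98 and -0.67 on its brightest probe set, Iglon5 -1.74 and -0.64, and the secreted protein gene Crispld2 1.71 and 0.68. The synaptic scaffold gene Bsn had -1.59 and -1.81. Gas7, a growth-arrest gene with a mean of -1.59, was lower on all 4 of its probe sets above the median signal, and its brightest went from 683 with PBS to 327 with Nell-1. Zdhhc21, a palmitoyltransferase, and Pappa, a protease of insulin-like growth factor binding proteins, were higher, at 0.84 and 0.77 on their brightest probe sets. Egr2 (-0.91), Ociad2 (-1.13) and Rgs16 (-0.68), a regulator of G-protein signalling, were lower by the same measure.

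Immediate-early genes, the classical transcripts induced without new protein, included more genes at least 1.5-fold lower than higher with Nell-1. The same held for all genes above the median signal, with 874 lower and 529 higher. Egr1, a zinc-finger transcription factor, measured 1293 with PBS and 506 with Nell-1, 2.56-fold lower. Fos (343 and 168) was 2.04-fold lower, Nr4a3 (153 and 73.1) 2.10-fold lower and Jun (2963 and 1970) 1.50-fold lower, on 1 of 2 probe sets. Junb (log2 ratio -0.06), Myc (-0.06), Atf3 (-0.08) and Nr4a1 (-0.02) differed by less than the robust SD at their signal. Egr3 was 2.05-fold higher on its brightest probe set (80.8 and 166). The mean over its 2 probe sets was -0.34, with the second below the median of the mean signal (77.7 and 23.5). Csrnp1 (296 and 454), named after its values were seen, was 1.53-fold higher. Of 24 transcription factors in this list, 2 were at least 1.5-fold higher, 6 at least 1.5-fold lower and 16 neither. The median of -0.18 lay at percentile 3.11 of matched random lists, inside the limits. The list of 24 other immediate-early genes had a median of -0.31, lower than all 10000 random lists, although only 2 passed 1.5-fold, both lower. Across this list, 16 further probe sets above the median signal had a smaller median of -0.11, with 11 lower and 5 higher. The list's members included Ier3, a stress-response gene (3720 and 2678), Hbegf, an EGF receptor ligand (1172 and 837), and Zfp36, which promotes mRNA decay (249 and 174). They were 1.39-fold to 1.44-fold lower on their brightest probe sets, and Hbegf was 1.64-fold lower on its second. Ier5l was 1.68-fold lower on its brightest probe set, while the mean over its 2 probe sets was 1.44 on the log2 scale. Its second probe set was below the median of the mean signal (6.39 and 78.4). Fosb was below the median signal on both arrays, at 25.4 and 7.29.

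Feedback inhibitors of MAP kinase signalling were lower as a group. Of 13 measured, 9 were at least 1.5-fold lower with Nell-1, 1 was higher and 3 were neither. The median log2 ratio was -0.65, lower than all 10000 matched random lists, whose central 95% ran from -0.31 to 0.21. Dusp1, a phosphatase that inactivates MAP kinases, went from 6875 with PBS to 3209 with Nell-1, 2.14-fold lower. Dusp2 (163 and 76.8) was 2.12-fold lower and Spred2 (376 and 190) 1.98-fold lower, on both of the Spred2 probe sets above the median signal. Dusp5 was 1.63-fold higher (214 and 349), and Spred1 (426 and 612), named after its values were seen, was also higher without reaching 1.5-fold. Across the group, 10 further probe sets above the median signal had a smaller median of -0.13, with 7 lower and 3 higher. RNA control probe sets also differed between these arrays, which is a limit for the immediate-early genes as well. The 24 poly-A spike-in probe sets, several per bacterial RNA added before labelling, had a median log2 ratio of -0.49. All were lower on the Nell-1 array, while 18 hybridisation spike-ins had a median of -0.18. Whether this difference extends to transcripts of the cells was not tested, and the 12 reference genes had a median of -0.03.

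Interferon-stimulated genes were also lower with Nell-1. Of 13 measured, 8 were at least 1.5-fold lower, none higher and 5 neither, with a median log2 ratio of -0.83 at percentile 0.04 of matched random lists. Usp18, a negative regulator of interferon signalling, went from 279 to 118. Ifit1, an antiviral RNA-binding protein gene, went from 196 to 84.6, Irf7 from 91.3 to 41.7 and Irf9, a subunit of the interferon-activated ISGF3 complex, from 775 to 369. These are 2.10-fold to 2.37-fold lower. None of the members had a further probe set above the median signal. The poly-A spike-in difference of -0.49 was measured on added RNAs, and whether it extends to these genes was not tested. The inflammatory and NF-kB list did not stand apart, with a median of -0.14 at percentile 25.8, 4 genes at least 1.5-fold higher and 2 lower of 22. In it, the cytokine Il1b (36.0 and 101) and the chemokine Ccl2 (64.3 and 103) were higher, and Lif (124 and 57.9) was lower.

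**Figure D2:**
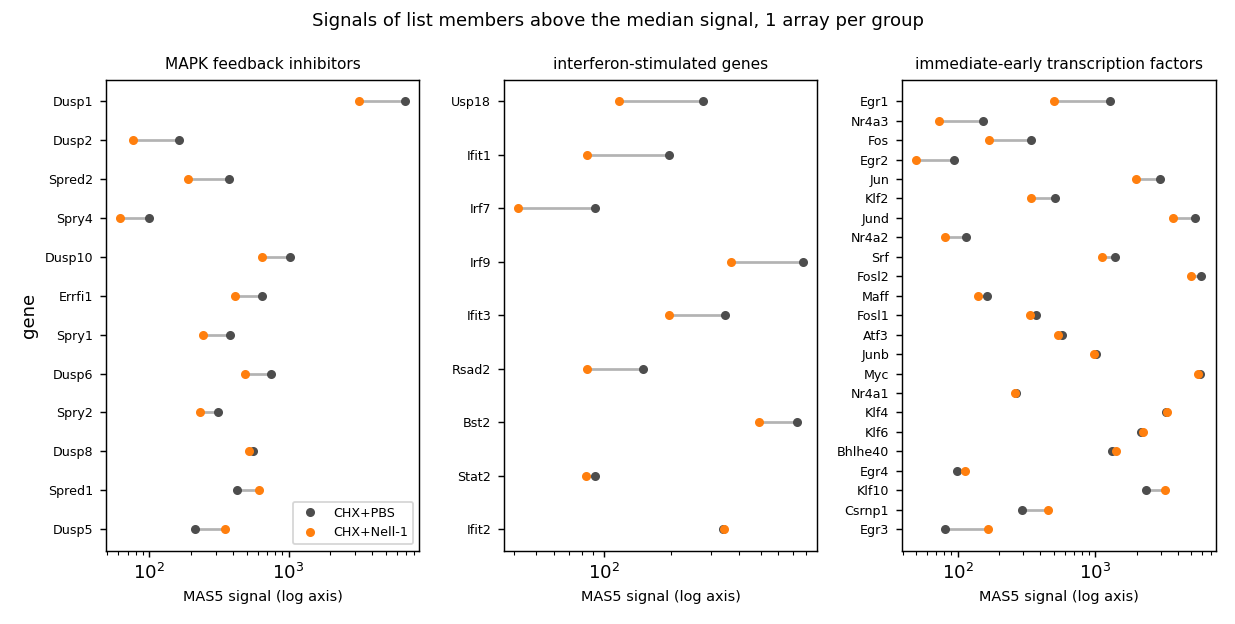
MAS5 signals on a log axis (x) for each gene (y) of 3 lists, members above the median signal only, with CHX+PBS in grey, CHX+Nell-1 in orange and 1 array per group, so no error is drawn. Dusp1 (6875 and 3209), Irf9 (775 and 369) and Egr1 (1293 and 506) are lower with Nell-1, while Dusp5 (214 and 349) and Egr3 (80.8 and 166) are higher.

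The NFAT and calcineurin pathway, in which calcium acts through the phosphatase calcineurin on NFAT transcription factors, did not stand apart as a list. Its 14 measured members were NFAT factors, calcineurin subunits and other regulators. Their median was -0.01 at percentile 54.5, with 1 higher, 1 lower and 12 neither. Nfatc4 was lower on all 3 probe sets above the median signal, with 3203 and 1852 on the brightest, 1.73-fold lower. Nfat5, which responds to osmotic stress, was 1.52-fold higher on its brightest probe set (370 and 564), and the mean over its 6 probe sets, 4 of them below the median signal, was -1.05. Nfatc2 had 3 probe sets above the median signal that disagreed. Signals were 133 and 103 on the brightest, 99.2 and 61.7 on the second, and 45.3 and 100.1 on the third, with log2 ratios of -0.36, -0.69 and 1.14. Nfatc1 (973 and 770) and Nfatc3 (1700 and 1983) did not reach 1.5-fold on their brightest probe sets, and of 5 Nfatc1 probe sets 1 was higher and 1 lower by 1.5-fold. Ppp3ca, a calcineurin catalytic subunit, was at 0.40.

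With signals as deposited, cartilage and bone lists lay inside the limits. Of 21 chondrocyte genes 2 were at least 1.5-fold higher, 7 lower and 12 neither, with a median of -0.37 at percentile 4.09. All 7 lower genes lay below the median signal, where 66.7% of probe sets passed 1.5-fold, and both higher genes lay above it. Without shared probe sets the chondrocyte median was -0.45, at percentile 1.54 and outside the limits, while the 10 members above the median signal had a median of 0.02, at percentile 67.1. Acan, encoding aggrecan, was 1.67-fold higher (176 and 293) and Sox6, a chondrogenic transcription factor, 1.62-fold higher (208 and 338), with 3 of its 4 probe sets past 1.5-fold. Col2a1, encoding cartilage collagen, was at 0.41 and Sox9, the master chondrocyte factor, at -0.39. Among 13 osteoblast genes, 1 was higher and 1 lower by 1.5-fold, both below the median signal. Alpl, the bone alkaline phosphatase, was at 0.55 and Sp7, encoding osterix, at 0.45, neither past 1.5-fold.

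Lists of developmental pathways lay inside the limits with signals as deposited. BMP and TGF-beta targets had a median of -0.14 at percentile 8.02, with 1 of 18 higher and 5 lower. Smad7, an inhibitor of this pathway, was 2.14-fold lower on its brightest probe set (1551 and 724), which is of the type shared between transcripts, and its unshared probe set gave 0.20. Tgfb2 was 1.59-fold lower (3179 and 1997) on its brightest probe set, and its other 3 above the median signal did not reach 1.5-fold. Wnt targets had a median of -0.28 at percentile 6.84, with 4 of 14 lower and none higher, among them Lgr5 (382 and 208) and Nkd2, a Wnt antagonist lower by 1.5-fold on 3 of 4 probe sets. As a mean over probe sets the Wnt median was -0.54, and over members above the median signal -0.32, both outside the limits. Hedgehog (-0.03) and Notch (-0.25) lists lay at percentiles 52.3 and 30.1. Nell1 itself was below the median signal on both arrays, at 4.50 and 6.48. Among reported receptors, Itgb1, encoding integrin beta 1, was 1.73-fold higher (1830 and 3159), past 1.5-fold on 2 of 3 probe sets. Its list was at percentile 46.0.

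A further pair of lists lay on the high side with small ratios. The 24 proliferation genes had a median of 0.14, at percentile 99.3, with 19 above 0 and none at 1.5-fold. The largest were Birc5, encoding survivin (4164 and 5788), Bub1, a spindle checkpoint kinase (591 and 814), Top2a, a topoisomerase of dividing cells (2098 and 2883), and Ccne2, a cyclin (698 and 949), at 1.36-fold to 1.39-fold higher. The 15 genes of cholesterol synthesis and its regulation had a median of 0.15 at percentile 97.9, and were inside the limits in 4 alternatives. Idi1, an isoprenoid isomerase, was 1.59-fold higher (1178 and 1873) and Hmgcs1, an early enzyme of the pathway, 1.31-fold (5792 and 7568).

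Stress, metabolic and ribosomal lists lay inside the limits. None of 16 genes of the unfolded protein and amino acid response reached 1.5-fold, with a median of 0.03. In the heat shock list (median -0.02), Hsp90aa1, an abundant chaperone, was the 1 of 11 past 1.5-fold, higher on all 3 probe sets above the median signal (5423 and 9044 on the brightest). The p53 targets (-0.17) included Cdkn1a, a cell-cycle inhibitor, at 1.89-fold higher (408 and 770) on 1 of 2 probe sets, and Bbc3, a pro-apoptotic gene, at 1.82-fold lower (288 and 159). Hypoxia and glycolysis genes (0.06) and 24 cytosolic ribosomal protein genes (-0.09) lay at percentiles 84.5 and 6.52. With signals as deposited, markers of other cell types also lay inside the limits. Percentiles were 51.4 for adipocyte, 16.03 for skeletal muscle, 12.3 for endothelial, 95.05 for haematopoietic, 59.4 for epithelial, 4.6 for fibroblast and mesenchymal, and 86.0 for neural markers. Above the median signal lay only 3 of 8 adipocyte, 2 of 10 skeletal muscle, 1 of 10 endothelial and 2 of 10 epithelial genes. The medians of these lists therefore rest mostly on unstable ratios. The 6 haematopoietic markers above the median signal were at percentile 47.97. Fibroblast markers above the median signal were outside the limits, at percentile 2.29, as were endothelial markers with low signals floored, at 1.61.

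**Figure D3:**
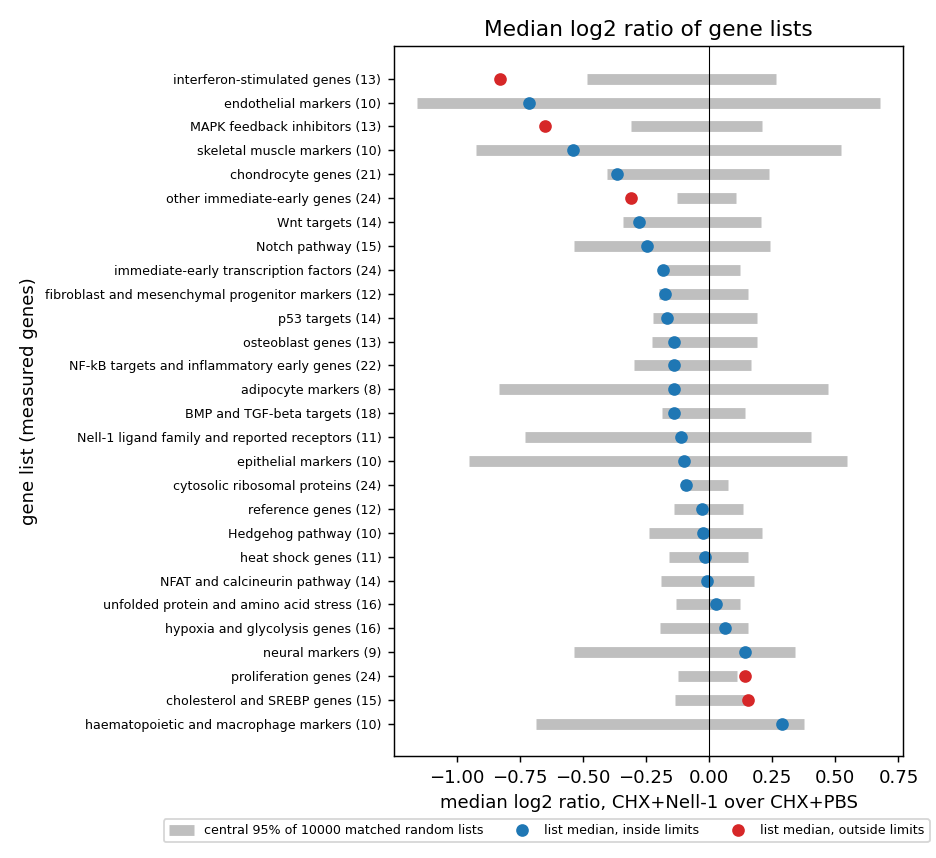
Median log2 ratio of CHX+Nell-1 over CHX+PBS (x axis) for 28 gene lists (y axis, with the number of measured genes), as points, over bars that span the central 95% of 10000 random lists matched on size and signal. The 5 red points outside their bars are interferon-stimulated genes (-0.83), MAPK feedback inhibitors (-0.65), other immediate-early genes (-0.31), proliferation genes (0.14) and cholesterol and SREBP genes (0.15).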

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

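Each group has 1 array, so leaving out a replicate was not possible. No paired analysis was possible because there is no second pair. Over all probe sets, 18282 passed 1.5-fold, against 10892 with 17.9 added to both signals, 10640 with signals floored at that value, 11932 at 2-fold and 5843 counted as genes. Above the median signal, 3254 passed, against 909 at 2-fold, 1403 counted as genes and 478 in the brightest 25% of probe sets. The share of passing probe sets that were higher was 43.2% over all probe sets and 44.8% after median centring. It was 50.4% with the loess trend removed and 50.1% after quantile normalization, which both pull the share toward balance by construction. Above the median signal the share was 41.3%, 45.6% after median centring, 49.1% with loess and 49.9% with quantile normalization. In the brightest 25% it was 55.0%. Same-sign pairs, 68.6% with r = 0.33, were 61.4% with r = 0.051 over all probe sets, 76.0% with r = 0.65 in the brightest 25%, 66.4% without shared probe sets, and had r = 0.37 with the added value. Of 269 alternative values for gene lists, 259 stayed on the same side of the limits and none of the lists that stood apart reversed. The cholesterol list came inside the limits at 0.13 after quantile normalization, 0.10 as a mean over probe sets, 0.11 without shared probe sets and 0.15 over members above the median signal. Wnt targets came outside them at -0.54 as a mean over probe sets and -0.32 above the median signal. So did chondrocyte genes at -0.45 without shared probe sets. Endothelial markers, with 1 of 10 above the median signal, came outside at -0.71 with the floor. Fibroblast markers did so at -0.17 above the median signal and -0.18 in the brightest 25%, the last added after seeing the data. Of 162 single genes, the 4 rescalings moved none by more than the robust SD at its signal, while the mean over probe sets moved 35 by more without changing a called direction, the added value 15, leaving out shared probe sets 10 and the floor 3. Median centring and the trimmed mean shift every gene alike and so cannot change a list's percentile. Their values for the lists are counted among the 259 and carry no information on stability. A mean over probe sets turned Nfat5 (-1.05), Egr3 (-0.34), Ier5l (1.44), Cdon (0.14), Plat (0.0429), Ptov1 (-0.23) and Lgr4 (-0.19), and leaving out shared probe sets turned Smad7 (0.20) and Ptov1 (-0.82). For Nfat5, Egr3, Ier5l and Cdon the mean took in probe sets below the median signal, while every probe set above it kept the called direction. The cause of the other reversals was not tested.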

Other observations

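Tests on the 5' over 3' signal and on the spike-in controls, the choice of genes by a mean signal over 1000, and the alternative of list members in the brightest 25% of probe sets were chosen only after the results were seen. The test of dim noise set beforehand named the brightest 25% of genes, which held 1 MAPK and 0 interferon members, and the brightest 25% of probe sets used in its place is that later choice. The limit of the scaling tests to loess and quantile normalization was also made later. The MAPK and interferon lists were weighed because they stood apart. Their medians were known before the tests were set, so what is said of them is a hypothesis. The other immediate-early, proliferation and cholesterol lists also stood apart and were not weighed. Their members in the brightest 25% of probe sets (20, 22 and 15) had medians of -0.29, 0.16 and 0.15. The percentiles were 0, 99.6 and 97.54.

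Abundant transcripts showed a further set of differences. Of 4478 genes with a mean signal over 1000, 76 were at least 1.5-fold higher and 57 lower with Nell-1. Among the lowest were Omd, encoding the bone and cartilage proteoglycan osteomodulin (2231 with PBS and 911 with Nell-1), Pgm5 (1944 and 873) and Sdc2, encoding the cell-surface proteoglycan syndecan 2. Sdc2 was lower on all 3 of its probe sets above the median signal, with 4827 and 2171 on the brightest. Hopx, a homeodomain-only protein gene (1625 and 734), was lower on both such probe sets, and Nbl1, a BMP antagonist gene (2432 and 1099.8), and Igfbp2, an insulin-like growth factor binding protein gene (1984 and 1039), on 1 each. Among the highest were Zfas1, a non-coding host of small nucleolar RNAs (3378 and 6416), the RNA-binding Pum3 (1825 and 3357), the mRNA export gene Sarnp (1879 and 3377), the mitochondrial import gene Timm8a1 (3115 and 5558) and the chromatin remodeller Smarca5 (1285 and 2260). Pum3, Sarnp and Smarca5 were higher on all 3 of their probe sets above the median signal. Ptov1 was 1.84-fold higher on its brightest probe set, but the mean over its probe sets was -0.23.

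The first pattern is the lower signal of MAPK feedback inhibitors with Nell-1, at a median log2 ratio of -0.65. Scaling between the arrays that depends on signal is argued against, since the median was still -0.61 after loess and after quantile normalization. The list also stayed below every one of 10000 random lists (highest percentile 0). That adds little, because the random lists were matched on signal and such scaling moves them largely with the list. Noise of dim probe sets is argued against only for the 6 members in the brightest 25% of probe sets. Their median was -0.64, at percentile 0.02 of random lists matched on signal. These 6 values are part of the pattern itself, and the test set beforehand held 1 member and gave no value. For the other members dim noise stays open. The 10 further probe sets of the members had a median log2 ratio of only -0.13, with 7 lower and 3 higher. A weaker 5' signal of RNA on the Nell-1 array stays open: the 5' over 3' log2 ratio of Actb and Gapdh changed by 0.0154 on average, but both lie near the top of the signal range, while the dimmer pyruvate carboxylase control was lower at its 5' probe set (206 with PBS and 66.2 with Nell-1) and its 3' probe set (537 and 413), with log2 ratios of 0.02 and -0.03 at the probe sets between. Nell-1 itself, and any difference between the 2 dishes in serum starvation or CHX exposure, may each produce such a pattern, and with 1 array per group these cannot be told apart.

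The second pattern is the lower signal of interferon-stimulated genes. Scaling between the arrays that depends on signal is argued against by the medians after rescaling. These were -0.75 after loess and -0.74 after quantile normalization, against -0.83 as deposited. The percentile of 0.04 after both adds little, because the random lists were matched on signal. Noise of dim probe sets stays open. The 9 members above the median signal were at percentile 0, which largely repeats the pattern, and only 2 members lay in the brightest 25% of probe sets, too few for the value that the MAPK list has. A weaker 5' signal, an effect of Nell-1 and a difference between the dishes all stay open.

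The third pattern is the lower signal of the poly-A spike-in controls on the Nell-1 array. Scaling between the arrays is argued against as the whole cause, since their median log2 ratio lay 0.32 below that of the hybridisation spike-ins (a difference of -0.32), more than the robust SD of 0.10 or 0.07 within either set. A weaker 5' signal in labelling may contribute, since 6 of 8 poly-A pairs had a lower 5' over 3' ratio with Nell-1. Their median change was -0.29, against 5 of 8 hybridisation pairs lower with a median of -0.02. The poly-A RNAs dap, lys, phe and thr are each read by more than 1 pair, so the pairs are not separate support. Neither phe pair fell (0.01 and 0.13). Nor are the robust SDs spreads between RNAs. The 3' probe sets were lower as well, from -0.53 (PheX) to -0.20 (Bs-lys), so a 5' loss is not the whole difference. The amount of spike-in added to each RNA sample is not given in the sources used here, and no biological explanation was tested.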
